A study of Mus musculus with 8 samples.

How the data were processed

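Bulk RNA sequencing had been carried out on F4/80hi cells sorted from the kidneys of C57BL/6 mice aged 10 weeks, in 8 libraries. The control group held 2 libraries of MHCII+ cells. After cisplatin, a platinum drug that damages kidney tubules and causes acute kidney injury (AKI), 3 libraries of MHCII+ cells and 3 of MHCII- cells had been made. Per the labels, all cells were CD45.2+, CD11b+, F4/80hi and negative for CD19, Ly6G and Ly6C. CD64 was named in the gate of the MHCII+ cells and was not named in that of the MHCII- cells. No control MHCII- library was analysed here. Cells were lysed on sorting, RNA was isolated with the PicoPure kit, cDNA was made with the SMARTseq v4 kit and libraries with the MicroPlex kit, per the labels' protocols. The cDNA kit does not keep strand, and 50.1% to 50.2% of stranded counts fell on the first strand, so unstranded counts were used. Genes that overlap an antisense partner cannot be separated in such counts.

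The authors deposited whole-number counts per gene from STAR, expected counts and TPM values from RSEM, and a table of TPM values for the series, with mm10 as the build. STAR, RSEM and mm10 are named per the submitters' processing notes, with no version. The annotation and the settings are not given in the sources used here. The deposited count files listed 24054 genes. The deposited TPM table held the RSEM TPM values themselves (largest difference 0 over 24027 genes matched by name). The other 27 names had no match in that table. Expected counts from the deposited RSEM files were rounded to whole numbers before use.

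Total gene counts were 13650152 and 17069748 in control MHCII+ replicates 1 and 2. They were 17936853, 19445301 and 19990445 in AKI MHCII+ replicates 1, 2 and 3. In AKI MHCII- replicates 1, 2 and 3 they were 17939356, 19712433 and 17302896. Between 13474 and 14215 genes had at least 1 count. In a single library, 3 counts corresponded to 0.143 to 0.238 CPM, counts scaled to the library total. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Summary lines that name no gene held 26.3% to 30.5% of reads and were left out of library sizes and tests. Reads outside annotated features were 16.6% ± 0.601 (SD, n = 2) in controls, 11.2% ± 1.10 (n = 3) in AKI MHCII+ and 11.6% ± 0.118 (n = 3) in AKI MHCII- libraries. Multimapping reads were 9.54% ± 0.319, 12.1% ± 0.885 and 12.1% ± 0.490 in the same order.

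Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling (factors 0.924 to 1.06), the filterByExpr filter and the quasi-likelihood F test. One fit held all 8 libraries in 3 groups, because the control group has 2 libraries. The common biological coefficient of variation was 0.159. Of 12021 genes tested, those with a Benjamini-Hochberg adjusted p below 0.05 were called, with no fold limit. Adjusted p-values of genes are from this test unless another is named. The standard error (SE) of a log2 fold change was approximated as its size divided by the square root of F. The comparisons were AKI MHCII+ against control MHCII+, AKI MHCII- against AKI MHCII+ and, as a secondary comparison, AKI MHCII- against control MHCII+. The first and the last share the control libraries, and the first and the second share the AKI MHCII+ libraries, so no overlap between them is given. Tests, groups, gene lists and most alternatives were fixed before the data were examined.

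The 35 fixed lists held 440 symbols, of which 421 were found in the files, 2 of them under an older symbol. They covered MHC class II and class I presentation, antigens of the gate, resident macrophages, monocytes, dendritic cells, neutrophils, T and NK cells, B cells, proximal tubule, distal nephron, tubular injury, endothelium, mesenchyme, podocytes, erythroid cells, sex-linked genes and mitochondrially encoded genes. They also covered type I interferon, interferon gamma, inflammatory cytokines, p53 targets, proliferation, alternative activation, lipid and lysosome, oxidative stress and iron, efferocytosis, complement, cholesterol synthesis, matrix and growth factors, glycolysis and hypoxia, oxidative phosphorylation, immediate early genes, endoplasmic reticulum stress and ribosomal proteins. None of the 18 mitochondrially encoded genes matched a name in the files, and none of the 8 erythroid genes passed the filter. The 28 lists with at least 4 tested members were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, with adjustment over the lists. The same test with an estimated correlation and limma's fry, which tests whether a list moves one way on balance, were run beside it. With an estimated correlation camera has few residual degrees of freedom, so a list it did not call is not shown to be unchanged. Fry does not set a list against the other genes. Where many genes change, its calls do not show that a list stands out.

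Genes named in the text were, per comparison, the 12 with the largest positive and the 12 with the largest negative fold changes. They had to be called, reach a mean of 5 CPM in the higher group and have groups that did not overlap. Members of the fixed lists, with those of smallest p as examples, and genes named by the gate or the treatment could also be named. Any other gene named is said to have been chosen after its values were seen. Where a group held 0 counts of a gene, the fold was computed against a floor of 3 counts over all libraries of that group. It is a lower bound. Where it held 1 to 3 counts, the ratio is given with its exact 95% counting interval. Coordinates are those of mm10, matched by symbol for 472 of 472 genes asked.

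Same-group libraries were compared by chi-square over genes. The lowest value per degree of freedom was 19.7, so no pair agreed within sampling noise. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries. Control replicate 1 has the genotype Clec9a-Cre/Cre Rosa-YFP/YFP and another run code than the other 7 libraries, and genotype, run and replicate cannot be separated. AKI libraries of both gates share numbers in the deposited names. Deviations from the group means correlated across genes at r = 0.240, 0.318 and 0.206 between same-numbered libraries, and at -0.203 to -0.0187 between the other pairs. Deviations of a gene cancel out within a gate, so the negative values follow from the positive ones and are not separate evidence. With so few libraries only a few pairings are possible, and the labels do not say what the numbers mark. That the numbers pair the libraries is therefore an assumption. A fit with the replicate number as a block was run on the 6 AKI libraries.

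The procedure was tested on simulated data with 200 changed genes, drawn from the real means and library sizes. Genes were drawn independently and with no pairing of libraries. Far more genes were called in the real data (4430, 1289 and 5696 in the 3 comparisons), and the adjusted threshold depends on that share. The recoveries below therefore do not carry over to the real comparisons. For AKI MHCII+ against control, 22.4%, 56.1% and 73.8% of genes changed by 1.5, 2 and 4-fold were called among 11793 genes tested. For genes of at least 5 CPM these shares were 29.4%, 70.6% and 97.8%. In AKI MHCII- against AKI MHCII+, 42.4%, 70.1% and 86.4% were called (11817 tested), and in AKI MHCII- against control 15.2%, 73.1% and 85.9% (11822 tested). Unchanged genes made up 5.66%, 8.33% and 5.00% of the calls in the 3 comparisons. A first criterion on the recovery of 4-fold changes was set higher than the 73.8% reached in the first comparison and was missed. After that result it was replaced by limits on the slope of fitted on true fold changes (within 0.1 of 1) and on false calls (under 15%), which all 3 comparisons met.

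Alternatives were DESeq2 1.42.0, RLE and upper quartile scaling, no filter, a filter of 5 CPM in 2 libraries, RSEM expected counts, limma-trend on log2(TPM + 1) and on log2(TPM + 0.1), robust quasi-likelihood, glmTreat against a fold of 1.5, a fit of the compared groups alone, the replicate block and leaving out each library. The TPM fits kept genes of at least 1 TPM in 2 libraries. Removal of AKI number 2 from both gates, and the block with an estimated correlation in camera, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Multi-copy genes such as ribosomal proteins, Gapdh, the Gbp family and Hspa1a and Hspa1b are uncertain, because reads can be shared with near-identical copies.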

Results

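Gene expression was measured by bulk RNA sequencing in F4/80hi cells of the mouse kidney, a gate that holds renal macrophages, without injury and after cisplatin-induced acute kidney injury (AKI). The groups were control MHCII+ (n = 2), AKI MHCII+ (n = 3) and AKI MHCII- cells (n = 3). Control replicate 1 had the genotype Clec9a-Cre/Cre Rosa-YFP/YFP and another run code than all other libraries, which bears on every comparison with control. MHCII is the surface molecule that presents antigen to CD4 T cells. Total gene counts per library ranged from 13650152 to 19990445. Values are CPM as mean ± SD of the libraries of a group, and log2 fold changes are given ± SE. Genes of the MHC class II list took 16.4% ± 0.876 of counts in control, 5.72% ± 0.615 in AKI MHCII+ and 2.36% ± 0.140 in AKI MHCII- libraries. Cd74, the invariant chain, took 9.71% ± 0.327, 3.50% ± 0.330 and 1.23% ± 0.153 on its own.

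The first comparison asked how MHCII+ F4/80hi cells sorted after cisplatin differed from those sorted from uninjured kidneys. In AKI MHCII+ cells, 9 of 11 tested genes of MHC class II presentation fell. Of 19 tested targets of p53, the transcription factor of the DNA damage response, 15 rose. Each list had adjusted p = 0.186 in camera with an estimated correlation and 0.000145 by fry. H2-Ab1, the beta chain of I-A, fell from 27438 ± 3692 CPM in controls (n = 2) to 5661 ± 1117 (n = 3), a log2 fold change of -2.28 ± 0.21. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 112 ± 7.87 to 958 ± 173 CPM (3.10 ± 0.17). Itgam, which encodes CD11b of the gate, rose from 169 ± 52.8 to 1771 ± 175 CPM (3.39 ± 0.21). Of kidney tubule genes, 5 of 7 proximal and 5 of 9 distal genes tested were lower after AKI, with adjusted p = 0.565 for each list with an estimated correlation, and the distal call was also lost by fry and without control replicate 2 (adjusted p = 0.0570 and 0.0679).

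Of 11 tested MHC class II genes, 9 were lower, 1 was higher and 1 did not pass, with the same counts adjusted over the list alone. The list's median log2 fold change was -2.09. Ciita, the master activator of class II transcription, fell from 584 ± 130 to 50.9 ± 16.4 CPM (-3.52 ± 0.25, adjusted p = 4.03e-05). Ciita lies on chromosome 16 at 10480014 to 10531064. Cd74 (-1.58 ± 0.12) and H2-Ob (-2.46 ± 0.19), a chain of the H2-O chaperone, were also lower. The gene that was higher was Ctss, a protease that cleaves the invariant chain (0.37 ± 0.13). Its call was lost without control replicate 1 (adjusted p = 0.123) or 2 (0.145), AKI MHCII+ replicate 1 (0.125) or 3 (0.0771), or AKI MHCII- replicate 1 (0.0506) or 3 (0.0716). The list was called as lower (camera, adjusted p = 8.92e-05), with adjusted p = 0.186 with an estimated correlation and 0.000145 by fry.

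Of 19 tested p53 targets, 15 were higher and 4 did not pass, and 16 were higher adjusted over the list alone. Phlda3, a repressor of Akt, rose from 3.35 ± 1.60 to 95.0 ± 9.23 CPM (4.79 ± 0.23, or 5.42 without control replicate 2). Ccng1 (2.02 ± 0.13) and Bax (1.48 ± 0.10), a mediator of apoptosis, rose as well. Phlda3 lies on chromosome 1 at 135766085 to 135769134 and Cdkn1a on chromosome 17 at 29090979 to 29100722. The list's median was 1.28, also with Tnfrsf10b, which had 1 count in controls, at its ratio. The list was called as higher (camera, adjusted p = 2.58e-07), with adjusted p = 0.186 with an estimated correlation and 0.000145 by fry.

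Of 16 tested oxidative phosphorylation genes, 14 were higher and 2 did not pass, also adjusted over the list alone. Cox5a, a subunit of cytochrome c oxidase, rose from 49.5 ± 0.232 to 140 ± 13.4 CPM, and Atp5o (0.88 ± 0.09), of ATP synthase, also rose. Of 18 ribosomal protein genes, 12 were higher, or 14 adjusted over the list alone, among them Rpl8 (0.94 ± 0.11) and Rpl4 (0.84 ± 0.12). Of 13 glycolysis and hypoxia genes, 6 were higher by both adjustments, with Ldha at 1.28 ± 0.12 and Pkm at 0.92 ± 0.09. Adjusted p of camera was 1.49e-05, 0.000122 and 0.00524 for these lists. With an estimated correlation the adjusted p was 0.186, 0.565 and 0.565, and by fry 6.80e-05, 0.0131 and 0.00819. Between the same libraries, reads outside annotated features were 16.6% ± 0.601 in control and 11.2% ± 1.10 in AKI MHCII+ cells, and multimapping reads 9.54% ± 0.319 and 12.1% ± 0.885.

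Of 13 genes of the interferon gamma response, 9 were lower, 1 was higher and 3 did not pass, also adjusted over the list alone. Cxcl9, a chemokine for T cells, fell from 64.4 ± 12.1 to 4.15 ± 1.03 CPM (-3.95 ± 0.30), and Gbp2 had a log2 fold change of -1.40 ± 0.18. The list includes Ciita, which also belongs to the class II list. Camera gave adjusted p = 0.00495, and adjusted p = 0.565 with an estimated correlation, and fry gave 0.0131. Of 17 inflammatory cytokine genes, 4 were higher and 13 did not pass, also adjusted over the list alone. Ccl2 (2.53 ± 0.38) and Ccl7 (2.82 ± 0.49), which attract monocytes, were among those higher. Camera gave adjusted p = 0.0430 for this list, and adjusted p = 0.654 with an estimated correlation. The call was lost without control replicate 2 (adjusted p = 0.0803), AKI MHCII+ replicate 1 (0.101) or AKI MHCII+ replicate 3 (0.0976), and fry gave 0.124.

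The type I interferon list was not called (camera, adjusted p = 0.0628), with 8 of 18 members higher and 1 lower by both adjustments. Irf7 (1.05 ± 0.15) and Usp18 (0.88 ± 0.11) were higher, and Stat1 (-0.91 ± 0.14) was lower.

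Of 7 tested proximal tubule genes, 5 were lower, or 7 adjusted over the list alone, with a median of -4.14, also with Miox at its ratio, or -1.70 on log2(TPM + 1), a scale that understates changes of low genes. Miox had 76 counts over both control libraries and 2 over the 3 AKI MHCII+ libraries, a 76.4-fold lower level (95% counting interval 20.4 to 643). Without control replicate 1 this ratio was 43.1 (10.7 to 376), without control replicate 2 119 (31.3 to 1009) and without AKI MHCII+ replicate 3 49.8 (13.3 to 419), and without AKI MHCII+ replicate 2, which held both counts, it was at least 33.3. Pck1, an enzyme of gluconeogenesis, fell from 5.04 ± 0.615 to 0.395 ± 0.269 CPM (-3.64 ± 0.81). Its call was lost without control replicate 1 (adjusted p = 0.0531), and its log2 fold change was -4.35 without AKI MHCII+ replicate 2. Of 9 distal nephron genes, 5 were lower, or 7 adjusted over the list alone, with Fxyd2 falling from 42.6 ± 4.99 to 7.79 ± 4.94 CPM (log2 fold change -3.06 without AKI MHCII+ replicate 2). Summed proximal genes gave 60.1 ± 6.64 CPM in controls and 8.96, 28.6 and 6.97 CPM in AKI MHCII+ replicates 1, 2 and 3. Summed distal genes gave 75.8 ± 14.3 CPM in controls and 8.79, 22.0 and 8.16 CPM in the same AKI MHCII+ replicates. Camera gave adjusted p = 0.00391 and 0.0173, and adjusted p = 0.565 for both with an estimated correlation. Fry gave adjusted p = 0.00819 for the proximal list. The distal call was lost without control replicate 2 (adjusted p = 0.0679) and by fry (0.0570).

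The T and NK cell, endothelial and tubular injury lists were not called by camera, though fry gave adjusted p = 0.0174 for tubular injury. The neutrophil, B cell, mesenchymal, podocyte and erythroid lists had fewer than 4 tested members and were not tested as lists. Neutrophil genes summed to 99.1 ± 33.3 and 62.5 ± 4.34 CPM, and B cell genes to 109 ± 2.21 and 59.0 ± 11.1 CPM in control and AKI MHCII+ libraries. T and NK cell genes summed to 0.635 and 13.6 CPM in control replicates 1 and 2, on either side of the 3.51 ± 2.06 CPM in AKI MHCII+ libraries. Erythroid genes summed to 0.0622 ± 0.0880 and 0.157 ± 0.0118 CPM, endothelial genes to 17.5 ± 2.92 and 12.1 ± 6.99 CPM, and mesenchymal genes to 4.05 ± 2.02 and 5.52 ± 3.25 CPM. Of 9 tested T and NK cell genes 0 passed in edgeR, with 2 at an unadjusted p below 0.05 and 0 in DESeq2. Of 3 tested neutrophil genes 1 was lower, of 2 B cell genes 1 was lower, and the sex-linked gene tested, Xist, was lower (-0.88), a call lost without control replicate 1 (adjusted p = 0.0748). Of 4 endothelial genes 0 passed in edgeR or DESeq2, with 0 at an unadjusted p below 0.05. Of 3 mesenchymal genes 0 passed in edgeR, with 1 at an unadjusted p below 0.05 and 1 in DESeq2. The only tested podocyte gene, Synpo, which encodes an actin-binding protein, was higher (3.30, or 2.39 on log2(TPM + 1)). In the tubular injury list 2 of 6 were higher. They were Spp1 (2.52 ± 0.16), which encodes osteopontin, and Lcn2, which was at least 13.4-fold higher than 0 control counts, a bound of 7.52 and 5.90 without control replicate 1 or 2. That list's median was 1.19, or 0.76 with Lcn2 and Havcr1 at their bounds.

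Of 16 resident macrophage genes 4 were higher, 5 lower and 7 did not pass (4 and 6 adjusted over the list alone). Tmem119 (1.73 ± 0.22) and Itga9 (-1.70 ± 0.25) were examples. Of 10 monocyte genes 4 were higher and 1 lower by both adjustments, with Ms4a4c at 1.29 ± 0.18 and Fn1 at least 7.95-fold higher than 0 control counts. The call of Fn1 was lost without control replicate 1 (adjusted p = 0.0757) or 2 (0.0861), where the bound was 4.46 and 3.50, and the bound was 5.25 without AKI MHCII+ replicate 1. Of 12 dendritic cell genes 5 were lower and 1 higher by both adjustments. Xcr1, a chemokine receptor of cross-presenting dendritic cells, was lower (-2.70 ± 0.31) and Itgax, which encodes CD11c, was higher (1.60 ± 0.23). Clec9a was 0.63 CPM in control replicate 1, which carries the Clec9a-Cre alleles, and 14.9 CPM in control replicate 2. Its log2 fold change of -3.15 ± 1.10 (adjusted p = 0.0467) became 0.46 without control replicate 2 (adjusted p = 0.838), -4.08 without control replicate 1 and -4.18 without AKI MHCII+ replicate 2. The call was also lost without AKI MHCII- replicate 1 (0.0517), AKI MHCII+ replicate 1 (0.119) or AKI MHCII+ replicate 3 (0.136). Adjusted p for the resident macrophage, monocyte and dendritic cell lists in camera was 0.935, 0.184 and 0.193. Fry called the monocyte list as higher (adjusted p = 0.0242) and the dendritic cell list as lower (0.0131). Summed monocyte genes were 461 ± 43.5 CPM in control and 635 ± 138 CPM in AKI MHCII+ libraries. Summed dendritic cell genes were 1081 ± 41.1 and 1467 ± 230 CPM, a rise opposite to the fry call.

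Antigens of the gate changed in opposite directions, with Itgam and Fcgr1 (0.54 ± 0.09) higher and Ptprc (-0.96 ± 0.10) and Emr1 (-0.82 ± 0.14), the older symbol of the F4/80 gene, lower. The remaining lists were not called by camera, while fry called complement (adjusted p = 0.000840) and lipid and lysosome genes (0.00388). Complement had 6 of 12 higher and 3 lower, with C5ar1 at 0.99 ± 0.12 and Cfh at -0.83 ± 0.11. In the matrix and growth factor list 4 of 14 were higher and 4 lower, with Mmp14 at 3.18 ± 0.20 and Mmp13 at -2.03 ± 0.21. The lipid and lysosome list had 4 of 16 higher and 2 lower, including Plin2 (1.39 ± 0.10), of lipid droplets. In the efferocytosis list, on uptake of dying cells, 3 of 14 were higher and 2 lower, or 4 and 3 adjusted over the list alone, with Cd300lf at 2.95 ± 0.29 and Mertk at 1.88 ± 0.33. Alternative activation had 2 of 10 higher and 2 lower (3 and 2 adjusted over the list alone), with Msr1 at 1.96 ± 0.15 and Mrc1 at -0.97 ± 0.13. Iron and oxidative stress had 3 of 13 higher and 2 lower, with Slc40a1, the iron exporter, at -2.58 ± 0.32. Proliferation had 5 of 18 higher and 1 lower, including Tyms (0.91 ± 0.16). MHC class I presentation had 4 of 13 lower and 0 higher, including Psmb9 (-0.80 ± 0.13), with 5 members at an unadjusted p below 0.05 and 4 lower in DESeq2. Immediate early genes had 1 of 14 higher and 2 lower (1 and 1 adjusted over the list alone), endoplasmic reticulum stress 1 of 11 higher and 2 lower, and cholesterol synthesis 1 of 16 lower. In that last list 0 passed adjusted over the list alone, with 2 at an unadjusted p below 0.05 and 1 lower in DESeq2. Where not stated, the counts adjusted over the list alone were the same. The median and the camera direction differed in sign for gate antigens, efferocytosis, T and NK cells and immediate early genes, and the median and the mean for gate antigens, efferocytosis and endoplasmic reticulum stress. The medians of the efferocytosis, endoplasmic reticulum stress and B cell lists changed sign under another scaling or unit.

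Over all genes, 2384 were higher and 2046 lower in AKI MHCII+ than in control cells, of which 577 and 720 changed by at least 2-fold. Among the largest increases were Trem1, a receptor that amplifies inflammation, from 0.521 ± 0.385 to 305 ± 111 CPM (9.26 ± 0.58, adjusted p = 3.00e-05, or 10.22 and 8.58 without control replicate 1 or 2), and Clec4e, the receptor Mincle (5.94 ± 0.69). Ccl17, a chemokine for CCR4+ T cells, had 2 control counts and was 210-fold higher (95% counting interval 58.0 to 1739), and Trem3, with 3 control counts, was 66.6-fold higher (22.6 to 324). Ccl17 was 118-fold higher without control replicate 1 (32.5 to 975), 112-fold without AKI MHCII+ replicate 3 (30.8 to 930) and at least 61.6-fold without control replicate 2, which held both counts. Trem3 was 29.3-fold higher without control replicate 2 (9.95 to 143) and at least 37.3-fold without control replicate 1. Cdh1, which encodes E-cadherin, rose from 0.634 ± 0.335 to 86.0 ± 61.5 CPM, Spint1 from 5.55 and 3.86 CPM in control replicates 1 and 2 to 230 ± 98.6 CPM, and Epha2 from 0.764 ± 0.856 to 38.0 ± 13.1 CPM. In AKI MHCII+ replicate 2 Cdh1 was at 19.0 CPM, against 140 and 99.0 CPM in the other AKI MHCII+ libraries. The log2 fold change of Cdh1 was 7.74 without control replicate 2, and that of Epha2 4.79 and 7.85 without control replicate 1 or 2. Socs2, an inhibitor of cytokine signalling, rose from 0.767 ± 0.411 to 34.3 ± 21.1 CPM (log2 fold change 6.16 without control replicate 2 and 4.81 without AKI MHCII+ replicate 3). Among the largest decreases were Apol7c, 119-fold lower (40.0 to 581) with 3 counts after AKI, or 77.6-fold (26.1 to 380) and at least 77.3-fold without AKI MHCII+ replicate 2 or 3, Emr4 (-5.11 ± 0.54), Gbp2b (-5.46 ± 0.45) and Cmah (-3.84 ± 0.49, or -4.65 without AKI MHCII+ replicate 2). Of the called genes 4145 reached a mean of 5 CPM in the higher group and did not overlap between the groups. With no CPM limit, 61.3% of all tested genes did not overlap, where chance gives 20%. The count of lower genes was 1217 without control replicate 1 and 1356 without control replicate 2. In limma-trend on TPM the split was 3010 higher and 1529 lower (66.3% higher, against 53.8% in edgeR), or 3022 and 1431 (67.9%) with the smaller pseudocount. With upper quartile scaling it turned, with 2065 higher and 2282 lower (47.5%).

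**Figure D1:**
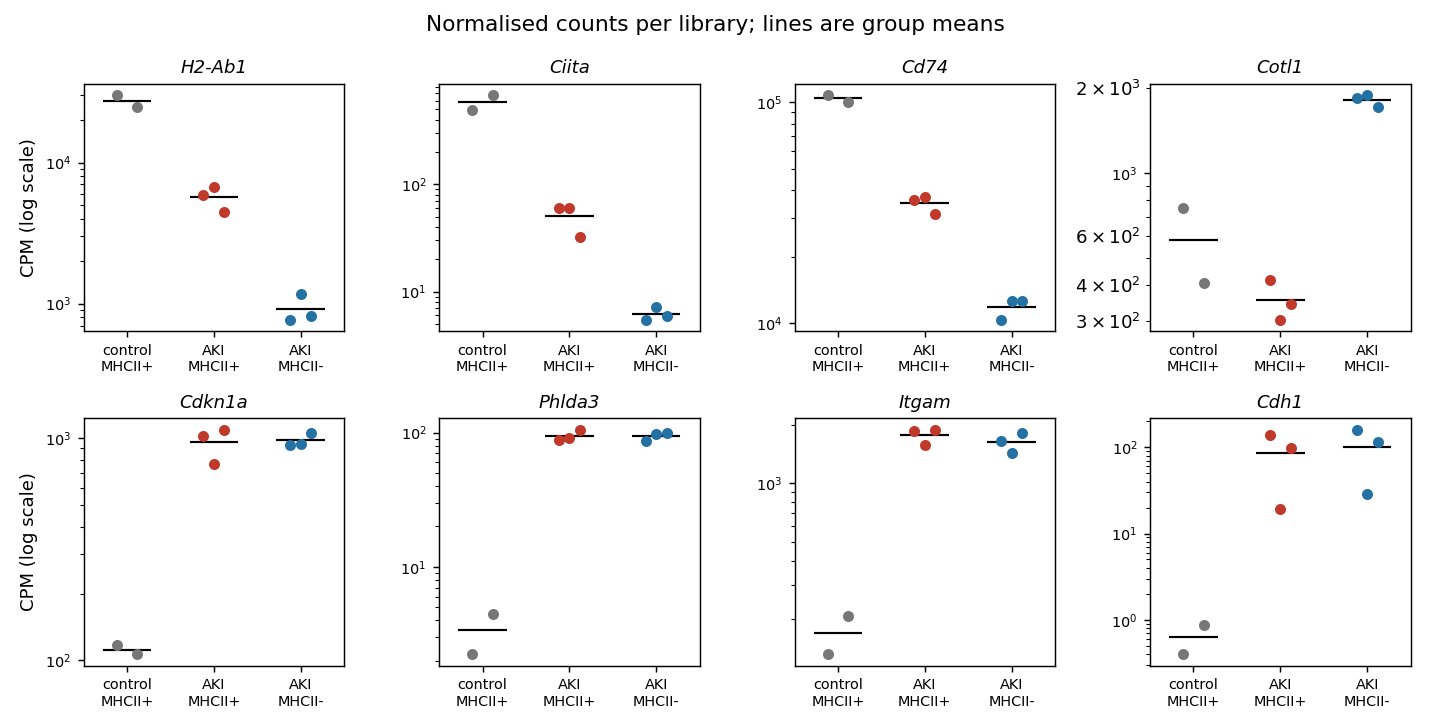
CPM on a log scale of 8 genes in each library of the 3 groups, with a point per library and a line at the group mean. Mean H2-Ab1 falls from 27438 CPM in control to 5661 in AKI MHCII+ and 919 in AKI MHCII- cells, while mean Cdkn1a is 112, 958 and 977 CPM.

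The next comparison asked how MHCII- and MHCII+ cells of injured kidneys differed. Unless the replicate block is named, its tests were run without it and leave differences between numbers in the spread. Of 11 MHC class II genes 6 were lower in MHCII- cells (adjusted p = 0.216 for the list with an estimated correlation), as the sort on that protein selects, so their direction is not independent of the gate. H2-Ab1 was 919 ± 217 CPM in AKI MHCII- and 5661 ± 1117 CPM in AKI MHCII+ cells (-2.62 ± 0.20, n = 3 each), and Ciita 6.20 ± 0.879 and 50.9 ± 16.4 CPM (-3.03 ± 0.26). Cotl1, an actin-binding protein, had the largest increase among called genes of at least 5 CPM in the higher group whose groups did not overlap, at 1810 ± 87.8 against 355 ± 59.5 CPM (2.35 ± 0.21). Of 16 genes of oxidative phosphorylation 10 were higher and 6 did not pass (list median 0.34, adjusted p = 0.216 with an estimated correlation). Of 19 p53 targets 4 were lower and 15 did not pass (8 lower and 1 higher with the replicate block), the latter including Cdkn1a (0.03 ± 0.13) and Phlda3 (-0.01 ± 0.15).

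Of 11 class II genes 6 were lower and 5 did not pass, also adjusted over the list alone. H2-Aa (-2.77 ± 0.21), H2-Eb1 (-2.65 ± 0.19), Cd74 (-1.56 ± 0.11) and H2-DMb1 (-0.97 ± 0.11) were lower. H2-DMa (0.01 ± 0.11), H2-Oa (0.09 ± 0.28) and H2-Ob (-0.37 ± 0.18) did not pass. Camera gave adjusted p = 2.99e-05, and adjusted p = 0.216 with an estimated correlation, and fry gave 0.000398. Of 16 oxidative phosphorylation genes 10 were higher and 6 did not pass, and 14 were higher adjusted over the list alone. Uqcrc1, of complex III, was at 0.50 ± 0.08 (adjusted p = 0.0136), and its call was lost without AKI MHCII+ replicate 1 (adjusted p = 0.0556) or AKI MHCII- replicate 2 (0.0516). Camera gave adjusted p = 5.13e-06, and adjusted p = 0.216 with an estimated correlation, and fry gave 0.000398. Of 18 ribosomal protein genes 0 passed in edgeR, also adjusted over the list alone, with 10 at an unadjusted p below 0.05 and 4 higher in DESeq2. With the replicate block 10 were higher. As a list they were called as higher (camera, adjusted p = 0.00690), with adjusted p = 0.828 with an estimated correlation. That call was lost by fry (0.198) and without AKI MHCII+ replicate 2 (0.0602) or AKI MHCII- replicate 3 (0.0515).

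With all 8 libraries and no block, camera called no list besides these 3. Still with no block, it called 5 lists when AKI MHCII- replicate 1 was left out, 6 when AKI MHCII+ replicate 1 was, 8 when AKI MHCII+ replicate 2 was, and 6 when number 2 was left out in both gates. With the replicate block, fitted to all 6 AKI libraries, camera called 9 lists. Those added by the block were resident macrophage (higher, adjusted p = 0.0424), proliferation (higher, 0.0223), type I interferon (lower, 0.0424), interferon gamma (lower, 0.0273), p53 targets (lower, 0.0273) and immediate early genes (lower, 0.000437). With the block and an estimated correlation, chosen after seeing the data, adjusted p was 0.636 to 0.708 for these lists, and 0.636 for the other 3 called. In that fit of 6 libraries, gate and number take up most degrees of freedom. The test could therefore hardly call a list, and it does not decide. In the resident macrophage list 4 of 16 were higher, or 5 adjusted over the list alone, and 9 were higher and 3 lower with the block. C1qc, a chain of complement C1q, was at 0.57 ± 0.09, and its call was lost without AKI MHCII- replicate 2 (adjusted p = 0.0516). Trem2, a lipid receptor of macrophages, was at 1.17 ± 0.25 (adjusted p = 0.0239). Its call was lost without AKI MHCII- replicate 1 (0.0590), AKI MHCII+ replicate 1 (0.0755), AKI MHCII- replicate 2 (0.0791) or AKI MHCII+ replicate 3 (0.0648). In the type I interferon list 5 of 18 were lower and 1 higher (7 and 1 adjusted over the list alone, 9 and 2 with the block). Of 19 p53 targets 4 were lower (5 adjusted over the list alone), and 8 were lower and 1 higher with the block. Of 13 interferon gamma genes 2 were lower by both adjustments, and 6 with the block. Of 14 immediate early genes 1 was lower (2 adjusted over the list alone), and 11 with the block. Proliferation had 1 of 18 higher by both adjustments, and 4 with the block.

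Monocyte and dendritic cell markers included Ccr2, the receptor for Ccl2, which fell from 220 ± 43.9 to 88.2 ± 4.36 CPM (-1.32 ± 0.14, adjusted p = 0.00442), and Dpp4 (-1.65 ± 0.21). In these lists 2 of 10 and 3 of 12 were lower by both adjustments, and 4 and 3 with the block. Axl, a receptor for dying cells, fell from 2156 ± 175 to 1219 ± 41.1 CPM (-0.82 ± 0.10) and was the only member of 14 called in the efferocytosis list, with 2 lower adjusted over the list alone, and 3 higher and 4 lower with the block. Tgfb1 (-0.62 ± 0.10) was the only one of 14 matrix and growth factor genes called, with 2 lower adjusted over the list alone and 5 with the block. Complement had 3 of 12 higher (4 adjusted over the list alone), and fry called it as higher (adjusted p = 0.0174) where camera did not (0.230). MHC class I presentation had 3 of 13 higher and 2 lower (5 and 2), lipid and lysosome 2 of 16 higher (3), glycolysis and hypoxia 2 of 13 higher and 1 lower (2 and 1). Iron and oxidative stress had 1 of 13 higher (1), and cholesterol synthesis 1 of 16 lower (0). Values in these parentheses are those adjusted over the list alone. In the cholesterol list 1 was at an unadjusted p below 0.05. With the block higher and lower members were 6 and 2 for complement, 6 and 4 for MHC class I and 6 and 2 for lipid and lysosome. They were 4 and 4 for glycolysis and hypoxia, 2 and 2 for iron and oxidative stress, 1 and 3 for cholesterol synthesis and 1 and 6 for class II. Of inflammatory cytokine genes (17 tested) 0 passed in edgeR, with 0 at an unadjusted p below 0.05 and 0 in DESeq2, and 3 were higher and 6 lower with the block. The same counts without the block were 0, 1 and 0 for alternative activation (10 tested) and 0, 1 and 1 for endoplasmic reticulum stress (11 tested). With the block both had 4 higher and 1 lower.

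Gate antigens Itgam (-0.12 ± 0.16), Emr1 (0.00 ± 0.12), Ptprc (-0.19 ± 0.09) and Fcgr1 (0.14 ± 0.08), which encodes CD64, did not pass, though with the block Ptprc (adjusted p = 0.0253) and Fcgr1 (0.0431) did. Proximal and distal tubule genes summed to 15.6, 29.8 and 8.21 CPM and to 12.6, 21.4 and 7.77 CPM in AKI MHCII- replicates 1, 2 and 3. In AKI MHCII+ replicates they were 8.96, 28.6 and 6.97 CPM and 8.79, 22.0 and 8.16 CPM. T and NK cell genes summed to 8.73 ± 5.12 and 3.51 ± 2.06 CPM, and neutrophil genes to 44.2 ± 3.18 and 62.5 ± 4.34 CPM. Of the proximal tubule, distal nephron, tubular injury and endothelial genes 0 passed in edgeR, with 0 at an unadjusted p below 0.05 and 0 in DESeq2. The same held for mesenchymal and podocyte genes and gate antigens. Of 9 T and NK cell genes 0 passed in edgeR or DESeq2, with 1 at an unadjusted p below 0.05. Neutrophil genes (lower), B cell genes (higher) and Xist (higher) had 0 passing in edgeR over all genes, and 1 each at an unadjusted p below 0.05, adjusted over the list alone, in DESeq2 and with the block. The median and the mean of the lipid and lysosome list differed in sign, as did the camera and fry directions of endothelial genes. Medians of the neutrophil, B cell, distal nephron, endothelial, mesenchymal, lipid and lysosome, and iron and oxidative stress lists changed sign under another scaling or unit.

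Over all genes, 559 were higher and 730 lower in AKI MHCII- than in AKI MHCII+ cells without the replicate block, with 10 and 75 at 2-fold or more. With upper quartile scaling the balance turned, to 731 higher and 665 lower (52.4% higher, against 43.4%). Besides Cotl1, Cd151, a tetraspanin, rose from 11.7 ± 0.819 to 27.2 ± 5.49 CPM (1.22 ± 0.16). Fmnl3, a formin, fell from 301 ± 25.7 to 91.8 ± 22.6 CPM (-1.72 ± 0.17), and Gpr141 (-2.12 ± 0.24), Klrb1b (-1.76 ± 0.28) and Card11 (-2.47 ± 0.35), an adaptor of NF-kB signalling, were lower. Cotl1 lies on chromosome 8 at 119809214 to 119840579. Of the called genes 1267 reached a mean of 5 CPM in the higher group and did not overlap between the groups. With no CPM limit, 34.8% of all tested genes did not overlap, where chance gives 10%. With the replicate block 1678 genes were higher and 1871 lower of 11461 tested, among them 1280 of the 1289 called without it. The counts without the block depended on each AKI library, and the block fit was not run with any library left out. Higher and lower genes were 19 and 178 without AKI MHCII+ replicate 1, 120 and 352 without AKI MHCII+ replicate 2, and 124 and 279 without AKI MHCII+ replicate 3. They were 200 and 472, 19 and 117, and 170 and 322 without AKI MHCII- replicates 1, 2 and 3. Without number 2 in both gates, an alternative chosen after seeing the data, 2 were higher and 48 lower. Of 48 named genes called in the fit without the block, 17 kept their call without any one library. Among them were Cotl1, Cd151, Ciita, Ccr2, Axl and Fmnl3. DESeq2 called 915 higher, and against a fold of 1.5 glmTreat called 1 and 7.

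**Figure D2:**
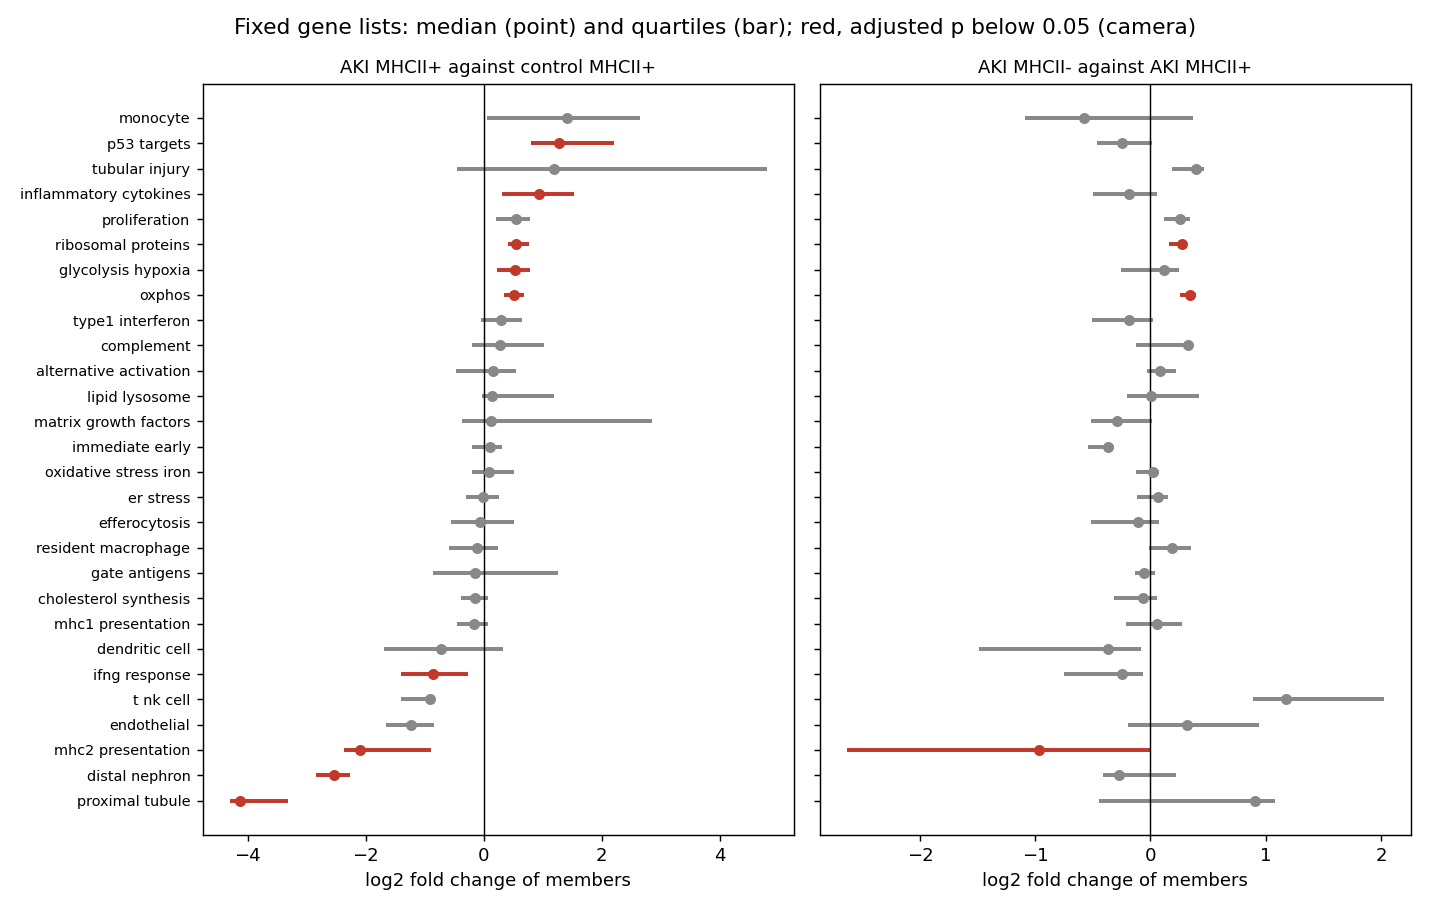
Median (point) and quartiles (bar) of the log2 fold changes of the tested members of 28 gene lists, for AKI MHCII+ against control and for AKI MHCII- against AKI MHCII+, with lists called by camera in red. The p53 list has a median of 1.28 in the left panel, and the class II list medians of -2.09 and -0.97.

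The secondary comparison set AKI MHCII- cells against control MHCII+ cells, which differ in both injury and gate. H2-Ab1 fell from 27438 ± 3692 CPM (n = 2) to 919 ± 217 CPM (n = 3), a log2 fold change of -4.90 ± 0.23, and Ciita fell by 6.55 ± 0.30 on the log2 scale. Phlda3 (4.78 ± 0.23), Cdkn1a (3.12 ± 0.17) and Itgam (3.28 ± 0.21) rose. Gbp2b, a guanylate-binding protein, was at least 429-fold lower, with 0 counts in AKI MHCII- cells, and Apol7c at least 118-fold lower. Without AKI MHCII- replicate 2 these bounds were 273 and 74.8. Trem1 (9.63 ± 0.59), Cdh1 (7.25 ± 1.30) and Adam8 (5.18 ± 0.37), a metalloprotease, rose. Without control replicate 2 Trem1 was at 8.95, Cdh1 at 7.97 and Phlda3 at 5.41, and without control replicate 1 Trem1 was at 10.60.

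Of 11 class II genes 9 were lower and 1 higher, of 19 p53 targets 14 were higher and 2 lower, and of 16 oxidative phosphorylation and 18 ribosomal protein genes 14 each were higher, all by both adjustments. Interferon gamma genes were 10 of 13 lower and 1 higher, glycolysis and hypoxia genes 9 of 13 higher and 1 lower, and distal nephron genes 6 of 9 lower, by both adjustments. The median and the mean of the gate antigen and of the matrix and growth factor lists differed in sign, and the efferocytosis median changed sign under another scaling or unit. Proximal tubule genes were 3 of 7 lower, or 4 adjusted over the list alone. Camera called these 8 lists, with adjusted p from 1.62e-06 for oxidative phosphorylation to 0.0443 for distal nephron. With an estimated correlation the lowest adjusted p was 0.261. The distal call was lost without control replicate 2 (adjusted p = 0.113), AKI MHCII- replicate 1 (0.0764) or AKI MHCII- replicate 3 (0.0596), and by fry (0.0523). Fry also called the dendritic cell list as lower (adjusted p = 0.00296) and the tubular injury (0.00989), lipid and lysosome (0.000952) and complement (0.000113) lists as higher. Over all genes 2833 were higher and 2863 lower. Among these, 5316 reached a mean of 5 CPM in the higher group and did not overlap between the groups. The balance of higher and lower genes turned with DESeq2 (2978 and 2779), RLE scaling (2912 and 2761) and on TPM (3260 and 2413 on log2(TPM + 1)), among other settings. Of all tested genes, with no CPM limit, 65.4% did not overlap, where chance gives 20%. With an estimated correlation camera called 0 lists in each comparison, with 3, 2 and 3 lists at an unadjusted p below 0.05, and fry called 12, 3 and 11.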

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

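Tests of the epithelial genes and control replicate 1, of reads shared by Cotl1 with copies, and of the depth and slopes of AKI number 2 were chosen after the result was seen, while those of the neighbours of Cotl1 and the splits of the libraries were set before.

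Cdh1, Spint1 and Epha2, genes usually described in epithelium, were higher in AKI cells of both gates. Epcam, Krt8 and Krt18 together reached at most 1.66 CPM in any AKI library, where Cdh1 was never below 19.0 CPM. They were chosen after a broader list of 14 epithelial genes had not decided. That list summed to 95.7 ± 11.3 CPM in control, 15.9, 46.4 and 16.0 CPM in AKI MHCII+ and 29.4, 43.9 and 16.6 CPM in AKI MHCII- replicates 1, 2 and 3. In replicate 2 of both gates the sum exceeded Cdh1 (19.0 and 28.6 CPM). Epcam, Krt8 and Krt18 were each at most 0.684 CPM in controls too, so they do not track the epithelial RNA present and cannot exclude it. The sum was lower in AKI libraries than in controls, where Cdh1 was higher. Epithelial RNA of the make-up seen in controls thus does not account for the rise, and other epithelial RNA stays open. Without control replicate 1, of another genotype and run, the smallest of the 3 log2 fold changes was 4.79 (largest adjusted p 0.0335, edgeR), which argues against that library as the source. Expression of these genes by the sorted cells after injury may remain as a hypothesis, and a change in which cells fall in the gate was not tested.

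Cotl1 was higher in AKI MHCII- than in AKI MHCII+ cells. STAR counts, which already leave out multimapping reads, gave a log2 fold change of 2.35. Expected counts from RSEM, which divide shared reads, gave 2.36. Reads shared equally with a copy were therefore not the source of the STAR value, and the RSEM value adds little to this. Tested genes within 500 kb (11 genes) had a median of -0.036 and ranged from -0.39 to 0.26, which argues against a change of the whole region. A difference between the cells of the gates may remain as a hypothesis, with the lack of CD64 in the label of the MHCII- gate as an open difference of the sort.

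AKI number 2 lay apart from the other AKI libraries in both gates. In 1 of the gates, MHCII+, its total count (19445301) lay between those of replicates 1 and 3 (17936853 and 19990445). There chi-square per degree of freedom was 22.7 between replicates 1 and 3, against 39.0 and 36.3 with number 2. This argues against sequencing depth in MHCII+. In MHCII- its count lay above both others (19712433 against 17939356 and 17302896), so depth stays open for that gate. Over genes called from the other replicates, the slope of number 2 on their log2 fold changes was 0.776 in MHCII+ and 0.873 in MHCII- cells. It was 0.946 to 1.06 for the others left out in the same way. Tubule genes were also highest in this number, at 28.6 and 29.8 CPM for the proximal list. A smaller response in number 2 is consistent with these slopes, and whether it differs in dose, timing or cell composition was not tested.

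For AKI MHCII- against AKI MHCII+, the 6 libraries make 10 splits, too few for a share under 0.05. The real split called 1289 genes, and the highest of the others 0 in edgeR, with 123 to 874 genes at an unadjusted p below 0.05 (3425 in the real split). For lists called by camera, 7 of the 10 splits gave as many as the real split, which called 3, and the highest other gave 13. The 3 other splits that part all 3 numbers called 0 to 1 lists, and the 6 that part only 1 number and keep the libraries of the other 2 together called 5 to 13. This points to a structure of the libraries by number, and with the replicate block 1678 genes were higher and 1871 lower.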

How the results depend on the processing

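The removal of AKI number 2 from both gates and the block with an estimated correlation were the alternatives chosen after the result was seen. Without 1 library, AKI MHCII+ against control gave 1676 to 2403 genes higher, 1217 to 2122 lower and 7 to 10 lists. AKI MHCII- against AKI MHCII+ gave 19 to 545 higher, 117 to 734 lower and 3 to 8 lists, and AKI MHCII- against control 2217 to 2755, 2038 to 2793 and 8 to 10. Fewer samples were fitted in these, without the block, and a group left with 1 library was assumed to vary like the others. Against a fold of 1.5, which asks for larger changes, glmTreat called 558 higher and 466 lower, 1 and 7, and 1076 and 928 in the 3 comparisons. In AKI MHCII- against AKI MHCII+ DESeq2 called 915 higher, for which the cause was not tested. The replicate block, which removes differences between numbers, gave 1678 higher, 1871 lower and 9 lists. Removal of number 2 gave 2 higher, 48 lower and 6 lists, with 2450 genes at an unadjusted p below 0.05. With an estimated correlation camera, limited by few residual degrees of freedom, called 0 lists in each comparison. With the block as well it called 0, with 0 at an unadjusted p below 0.05. That last test had few residual degrees of freedom and could hardly call a list. Clec9a in AKI MHCII+ against control ranged from -4.18 to 0.46 without 1 library. It reversed without control replicate 2, which left the library with the Clec9a-Cre alleles as the only control. Genotype and run of that library cannot be separated, and the cause was not tested. All other counts stayed within 1.5 times. The median log2 fold change of all genes in AKI MHCII+ against control was -0.01, and 0.10 on log2(TPM + 0.1), a shift that goes with the larger share of higher calls there. Of 3834 alternative values for 190 named results, 3516 kept direction and side of the threshold, 315 lost and 2 gained a call, and 1 reversed. The gains were Ptprc and Fcgr1 with the block, which changed no other call of a named gene. Counts of 0 to 3 limit folds of genes near 0.143 to 0.238 CPM, the level of 3 counts in a single library.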

Other observations

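The test of STAT5 targets was chosen after the result was seen, as were the genes Il2ra, Cish and Osm, which lie outside the rule for named genes.

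In AKI MHCII+ against control cells Il2ra, which encodes CD25, had a log2 fold change of 4.47 ± 0.73 (adjusted p = 0.00143, edgeR) and Cish 4.08 ± 0.57 (adjusted p = 0.000619), beside Socs2 (5.42 ± 0.75, or 6.16 without control replicate 2 and 4.81 without AKI MHCII+ replicate 3) and Ccl17, 210-fold higher (58.0 to 1739), or 118-fold and at least 61.6-fold without control replicate 1 or 2 and 112-fold without AKI MHCII+ replicate 3. Il2ra was 375 and 234 CPM in AKI MHCII+ replicates 1 and 3 and 92.0 CPM in replicate 2, against 9.12 and 11.8 CPM in controls.

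A hypothesis is that signalling through STAT5 may be higher in these cells. Of 6 other genes known as STAT5 targets, 4 were higher (Osm 2.68 ± 0.68, Bcl2l1 1.24 ± 0.12, Ccnd2 1.34 ± 0.16 and Socs3 2.27 ± 0.42). Pim1 did not pass (0.09 ± 0.35), and Myc was lower (-0.58 ± 0.18, adjusted p = 0.0317), against the hypothesis. The call of Osm was lost without control replicate 1 (adjusted p = 0.0790) or 2 (0.0868), and that of Myc without control replicate 1 (0.372) or AKI MHCII+ replicate 1 (0.0749), 2 (0.0673) or 3 (0.0697). Random lists of 6 genes matched on mean expression held 2.09 higher members on average, and 11.4% of 10000 held as many as 4, so the test does not decide. Socs3 and Osm also respond to other pathways, and no phosphorylation was measured.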
